A study of Homo sapiens with 30 samples.

How the data were processed

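RNA was sequenced from U-937 and SKNO-1 cells and from CD34-positive marrow cells of patients. Per the labels, the cell-line libraries were made from 1 ug of total RNA with a stranded kit after ribosomal depletion, and the patient libraries from 1 ng of RNA of bead-selected cells from frozen marrow with a low-input kit, also depleted of ribosomal RNA. Groups were taken from the labels: control, ATRA, TCP and ATRA+TCP in each line, with 2 libraries each, and baseline AML (6), baseline MDS (2), treated AML (4) and treated MDS (2) in patients. Whether cell-line replicates were separate cultures is not given in the sources used here, so their p-values measure the spread between these samples, which may be technical.

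Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.5.3a, RSEM 1.2.28 and DESeq2 were used with genome build hg38. The notes give no role or order, and the annotation release and strand setting are not given in the sources used here. The deposited gene tables hold raw expected counts, with 2 decimals and not all whole, for U-937, SKNO-1, baseline patients and treated patients. They were rounded to whole numbers before testing. The authors also deposited RPKM values, of which the cell-line table served for gene symbols and to check that its columns match the count columns. Over all genes, 11 of 16 RPKM columns had their highest Spearman correlation with the count column of the same name (0.896 to 0.906). After centring each gene with a mean count of at least 50 within its line, 16 of 16 did (own r from 0.949 to 0.977, next best at most 0.882). The patient RPKM tables, normalized separately, were not used.

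Each table held 60603 genes, and 58528 IDs were found in GENCODE 29 (GRCh38), which gave the positions, counted from 1. There were 1743 gene IDs whose symbol was shared with another ID, and these were kept apart by ID. In patients, 556 genes were left out of every test and gene value: XIST, TSIX and genes of the Y chromosome.

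Tests used R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with a gene called at an adjusted p below 0.05. Within a line, 1 fit over its 8 libraries gave ATRA+TCP, ATRA and TCP against control, ATRA+TCP against each single drug, and the interaction. A fit over the 16 cell-line libraries gave the difference between the lines. In patients, treated against baseline was fitted over 14 libraries with the disease (AML or MDS) as covariate, and AML against MDS over the 8 baseline libraries. The biological coefficient of variation was 7.46% in U-937, 6.38% in SKNO-1, 122% for treated against baseline and 127% for AML against MDS. Genes called in both lines were counted per direction beside the number expected of independent calls. No overlap is given between comparisons that share libraries.

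Fixed lists (32, with 539 symbols, of which 532 are in the tables) covered retinoid targets, LSD1-responsive genes, monocyte and macrophage, granulocyte, primary granule, NADPH oxidase, stem and progenitor, LSC17, mitosis, DNA replication, MYC and ribosome biogenesis, CDK inhibition and p53, interferon, MHC class II, MHC class I, inflammation, TGF-beta, cholesterol synthesis, lysosome and autophagy, mast cell, basophil and eosinophil, erythroid, megakaryocyte, T-cell, NK-cell, B-cell, plasma cell, stroma and endothelium, mitochondrial genome, immediate-early, heat shock, drug target and RUNX1-RUNX1T1 genes. Some genes stand on several lists, such as ITGAM on the LSD1-responsive and granulocyte lists. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), two-sided, with a preset correlation of 0.01 and adjustment over the lists. No list of any comparison passed with an estimated correlation. A list's members were also adjusted over the list alone. The genes that rose, and those that fell, in both lines were tested as lists in patients in the same way.

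Genes were named by a fixed rule: adjusted p below 0.05, a change of at least 2-fold, a mean of at least 5 CPM in the higher group, libraries of the groups not overlapping (cell lines), and a symbol that is not clone-based, non-coding by family name, histone, immunoglobulin, T-cell receptor or pseudogene-like. ATRA+TCP against control gives up to 8 genes per direction, other comparisons 4, and each list up to 4 members of lowest p; where fewer than 4 pass in patients, the lowest-p genes are given as not passing. KDM1A, RARA, RXRA, CYP26A1, ITGAM, CD86 and GFI1 are followed, and members named for ATRA+TCP are followed in other comparisons. Not every value of these genes is printed, so a missing value does not mean no change. The condition on overlap was not applied to the interaction and the difference between lines. Genes whose presence varies between people by haplotype were not named in patients, a departure made after the values were seen. The comparisons, tests, lists and this rule were set before the data were examined.

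Depth and the other library measures were taken from the rounded counts of all genes. Over a library, 3 counts correspond to 1.10 to 7.54 CPM in patients, 0.105 to 0.130 CPM in U-937 and 0.0795 to 0.138 CPM in SKNO-1. Where a group had 0 counts, a fold is given against 3 counts over the group; with 1 to 3 counts, a ratio has its 95% counting interval. Intervals and floors cover counting error alone. Reads of near-identical genes (FCGR2B, LILRA6, LILRB3, CEACAM, S100, HLA, NCF1, TPSAB1, HSPA1A, haemoglobin genes) can be split between copies, so their values are uncertain, as are those of antisense genes.

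In patients the pairing comes from the labels, which give the same donor for 3 pairs of libraries. Deviations from group means correlated at 0.174, 0.385 and 0.430 within these pairs and at a median of -0.106 between libraries of other patients (lowest -0.400, highest 0.518). Pairwise correlations of log2 CPM over all patient libraries ran from 0.213 to 0.884 (median 0.441), against 0.989 to 0.992 between cell-line replicates. No pair of replicates looked like a single library under 2 labels (chi-square per degree of freedom 4.07 to 25.5).

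The tests were run on simulated counts with known changes. For ATRA+TCP, 33 of 65 genes changed 1.5-fold, 48 of 64 changed 2-fold and 60 of 65 changed 4-fold were recovered in U-937 (16668 genes in the step), with 15 of 16474 unchanged genes called. In SKNO-1 (16062 genes) the numbers were 41, 45 and 58 of 66 each. For the interaction, 45 of 64 genes changed 2-fold were recovered in U-937 (16675 genes) and 43 of 66 in SKNO-1 (16003 genes), and for the difference between lines 42 of 64 (17729 genes). For treated against baseline (11124 genes), edgeR recovered 0 of 60, 0 of 60 and 0 of 58 at the 3 sizes, and DESeq2 0, 2 and 11, with 24 unchanged genes called. For AML against MDS (12362 genes), edgeR recovered 0 of 60, 0 of 61 and 0 of 59. A simulated list of changed genes was recovered in treated against baseline (adjusted p = 9.41e-06 by camera) and not in AML against MDS (adjusted p = 0.651), with 0 of 29 unchanged lists called in either. Simulated genes were drawn independently of each other. The lists left uncalled therefore cannot show how often the preset correlation gives false calls for correlated genes.

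Alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, a 2-fold minimum, the replicate number or patient as a block, limma-voom with the patient as a random block, no disease covariate, AML libraries alone, leaving out each library, and an estimated correlation. Added after seeing the data were the patient comparison on libraries with at least 1000000 counts and both patient comparisons without ribosomal RNA loci, RN7SL1, RN7SL2, RN7SK and mitochondrial genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.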

Results

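Gene expression was measured by RNA sequencing in 30 libraries of human myeloid cells. Of these, 16 came from the acute myeloid leukaemia (AML) models U-937, a line of monocytic character, and SKNO-1, a line that carries the RUNX1-RUNX1T1 fusion and grows with the cytokine GM-CSF. The other 14 came from CD34-positive cells, the fraction that holds stem and progenitor cells, of bone marrow from patients with AML or myelodysplastic syndrome (MDS). Each line was given vehicle (DMSO, called control below), all-trans retinoic acid (ATRA, a ligand of the retinoic acid receptors) at 1 uM, tranylcypromine (TCP, an inhibitor of the histone demethylase LSD1, whose gene is KDM1A) at 10 uM, or both drugs (ATRA+TCP) for 4 days, with 2 libraries per group. In U-937, the protocol label of TCP replicate 2 gives 1 uM instead of 10 uM. The patient libraries fall into 8 baseline samples (6 AML, 2 MDS) and 6 samples taken during treatment with both drugs (4 AML, 2 MDS), and 3 patients gave a sample to each group.

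Total counts ran from 23082395 to 28545580 per library in U-937 (median 24434805) and from 21750220 to 37722180 in SKNO-1 (median 31402542). The patient libraries were far smaller, with 534415 to 2728942 counts at baseline (median 1504539) and 397881 to 2529229 on treatment (median 1036800). They also held fewer genes, with 7477 to 20302 genes at 1 count or more against 21078 to 23922 in the lines. Their 10 most abundant genes took 16.5% to 59.4% of the counts, against 13.1% to 19.4% in the lines. Ribosomal RNA loci took 9.08% to 49.0% of patient counts and at most 0.0626% in the lines.

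**Figure D1:**
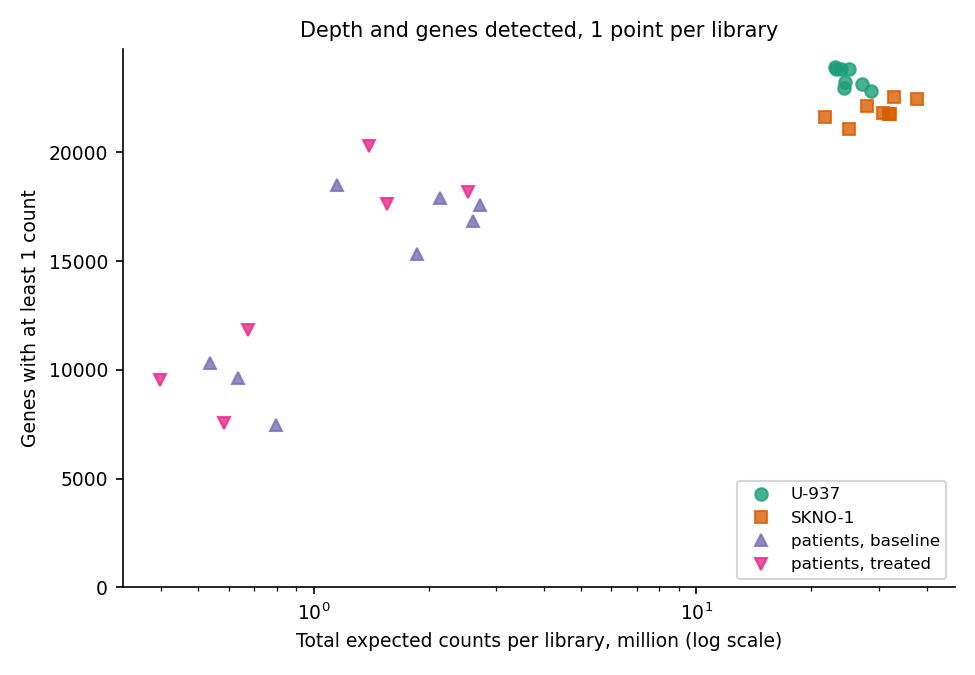
Genes with at least 1 count (vertical axis) against the total count of each library in units of 1000000 (horizontal axis, log scale), 1 point per library, with U-937, SKNO-1, baseline patients and treated patients in separate colours. The 16 cell-line libraries lie between 21078 and 23922 genes, and the 14 patient libraries between 7477 and 20302.

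The combination against control asked what both drugs together changed in each line. In U-937, ATRA+TCP raised genes of myeloid maturation, the interferon response and the lysosome, and lowered MYC with genes of ribosome biogenesis. As lists these passed by camera with its preset correlation, and 0 of 29 lists passed with an estimated correlation. ITGAM, which encodes the CD11b integrin of maturing myeloid cells, went from 37.4 ± 3.58 to 298 ± 18.7 CPM (counts per 1000000 library counts, mean ± SD, n = 2 per group), a log2 change of 2.99 ± 0.10 (SE, adjusted p = 4.88e-15 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for every adjusted p of a gene below). CD86, a costimulatory molecule of antigen-presenting cells, went from 0.783 ± 0.000292 to 35.2 ± 0.803 CPM (log2 change 5.48 ± 0.17, adjusted p = 2.09e-15). MYC, a transcription factor of growth and proliferation, fell by 2.62 ± 0.09 on the log2 scale. In all, 9885 of 17149 tested genes passed, 4897 higher and 4988 lower, and 3539 of them changed at least 2-fold (1612 higher, 1927 lower).

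The largest increases in U-937 included genes with hardly any counts in control cells. TNFSF15, a TNF-family cytokine (ENSG00000181634.8, chromosome 9, 114784635 to 114806126), had 0 counts in control and 15.2 ± 0.263 CPM with both drugs, which is at least 265-fold higher against a floor of 3 counts over the group. VSIG4, a complement receptor of macrophages, was at least 196-fold higher, and RARB, a retinoic acid receptor that retinoids induce (ENSG00000077092.19, chromosome 3, 25174332 to 25597932), at least 101-fold higher. TGM2, a transglutaminase induced by retinoids (ENSG00000198959.12, chromosome 20, 38127387 to 38166578), went from 0.114 ± 0.0501 to 121 ± 4.58 CPM (log2 change 9.98 ± 0.21, adjusted p = 3.64e-18). CEACAM1, a cell adhesion molecule with near-identical relatives, was 1249 times higher (95% counting interval 427 to 6060), ARL14EPL 654 times (117 to 25875) and the potassium channel gene KCNH4 247 times (84.0 to 1199). HNRNPLL, a splicing regulator, rose by 8.19 ± 0.19 on the log2 scale. Among the largest decreases, PWAR5, a transcript of the Prader-Willi region, had 503 counts in control and 0 with both drugs, at least 153-fold lower. The synaptic adhesion gene NRXN3 fell by 6.13 ± 0.19, the opioid precursor gene PDYN by 5.76 ± 0.26, the spectrin gene SPTB by 4.58 ± 0.22, TENT5C, which encodes a poly(A) polymerase, by 4.19 ± 0.12, the G-protein subunit gene GNAL by 4.02 ± 0.30 and TMEM163 by 3.52 ± 0.10. The antisense gene VLDLR-AS1 fell by 3.97 ± 0.22, a value that is uncertain because the strand setting of the counting is not given. KDM1A fell by 0.26 ± 0.08 (adjusted p = 0.00686) and RXRA, a partner of the retinoic acid receptors, by 0.43 ± 0.13 (adjusted p = 0.0136), while RARA rose by 0.28 ± 0.11 (adjusted p = 0.0288) and GFI1, a repressor that works with LSD1, by 0.35 ± 0.08 (adjusted p = 0.00110). CYP26A1, which encodes a retinoic acid hydroxylase, was too low to be tested in U-937.

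Of the 29 gene lists tested in U-937, 16 passed with ATRA+TCP, 14 higher and 2 lower. Among 31 interferon-stimulated genes, 29 rose and 1 fell (median log2 change 2.87, camera adjusted p = 2.22e-17). IFIT3 was at 5.54 ± 0.37, SAMD9L at 3.88 ± 0.11, SAMD9 at 3.02 ± 0.09 and IFI6 at 2.86 ± 0.09. In the granulocyte list, 15 of 16 genes rose (median 2.45, adjusted p = 5.56e-10). Among them were the calprotectin subunit S100A9 (7.43 ± 0.14), TREM1 (4.32 ± 0.17) and the granulocyte transcription factor CEBPE (2.13 ± 0.10). Of 22 monocyte and macrophage genes, 16 rose and 2 fell (median 1.30, adjusted p = 4.46e-07). MS4A6A was at 3.43 ± 0.11, CD68 at 3.02 ± 0.09 and MS4A7 at 2.91 ± 0.10. Genes chosen as responsive to LSD1 inhibition rose in 12 of 13 cases (median 2.03, adjusted p = 4.86e-08). LYZ, the gene of the antimicrobial enzyme lysozyme, was at 3.96 ± 0.11 and the protease CTSS at 2.03 ± 0.09. Retinoid targets rose in 13 and fell in 4 of 20 cases (median 1.38, adjusted p = 0.000309). The transcriptional repressor HIC1 was at 6.83 ± 0.19, DHRS3, a retinal reductase, at 5.26 ± 0.11 and CD38 at 4.41 ± 0.11. For each of these 5 lists the adjusted p was 0.109 with an estimated correlation in place of the preset one.

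All 20 lysosome and autophagy genes rose (median 1.08, adjusted p = 1.67e-12), with the cathepsins CTSD at 2.75 ± 0.12 and CTSA at 2.29 ± 0.08. All 6 subunits of the NADPH oxidase rose too (median 1.25, adjusted p = 5.38e-05), with CYBB at 3.83 ± 0.10 and NCF1, which has near-identical pseudogenes, at 6.39 ± 0.16. With an estimated correlation, both lists had an adjusted p = 0.178. MHC class I genes rose in 10 of 12 cases (median 0.67, adjusted p = 0.000309, and adjusted p = 0.187 with an estimated correlation), with PSMB9 at 1.31 ± 0.12 and TAP1 at 1.21 ± 0.11. Among NF-kB and inflammation genes, 14 of 19 rose and 1 fell (median 0.77, adjusted p = 0.000309, and adjusted p = 0.280 with an estimated correlation). IER3 was at 3.06 ± 0.26, the chemokine CXCL8 at 2.99 ± 0.26 and the cytokine IL1B at 2.72 ± 0.25. Cholesterol synthesis genes rose in 15 and fell in 1 of 19 cases (median 0.37, adjusted p = 1e-04). Heat shock genes rose in 9 and fell in 1 of 11 cases (median 1.04, adjusted p = 0.000313), with HSPA1A, which has a near-identical copy, at 2.88 ± 0.17. Genes of CDK inhibition and the p53 response rose in 8 and fell in 2 of 16 cases (median 0.29, adjusted p = 0.0430), with the CDK inhibitor CDKN1A at 3.08 ± 0.16 and the antiproliferative gene BTG2 at 2.97 ± 0.12. These last 3 lists had an adjusted p = 0.199 with an estimated correlation. Primary granule genes rose in 6 and fell in 1 of 11 cases (median 0.39, adjusted p = 0.00815), with SRGN at 3.27 ± 0.11. Genes of the TGF-beta response rose in 9 and fell in 2 of 16 (median 0.45, adjusted p = 0.0251), with THBS1 at 3.55 ± 0.22 and ID1 at 2.91 ± 0.15. With an estimated correlation, the latter 2 lists had an adjusted p = 0.429.

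The lists that fell in U-937 were MYC and ribosome biogenesis, in which 17 of 22 genes fell and 0 rose (median -0.63, adjusted p = 1.87e-06, and adjusted p = 0.280 with an estimated correlation), and the LSC17 genes, which make up a published leukaemia stem cell score. In the former, the polyamine synthesis gene SRM fell by 1.31 ± 0.09 and the pyrimidine synthesis gene CAD by 1.05 ± 0.08. Of 9 LSC17 genes, 7 fell and 1 rose (median -1.02, adjusted p = 0.0484, and adjusted p = 0.200 with an estimated correlation). They were tested as a list without weights, and the score itself was not computed. The fall of the list therefore does not give the direction of the score. CDK6, a cell-cycle kinase, fell by 1.98 ± 0.09 and AKR1C3, with 0 counts in control, was at least 23.7-fold higher. Mitosis genes did not pass as a list (2 higher and 9 lower of 23, adjusted p = 0.182), nor did DNA replication (9 and 3 of 24, adjusted p = 0.138), stem and progenitor genes (4 and 3 of 15, adjusted p = 0.576) or MHC class II (3 and 3 of 7, adjusted p = 0.923). The class II members moved apart, with the invariant chain CD74 at -0.57 ± 0.08 and HLA-DMB at 1.56 ± 0.22. Counts adjusted over the list alone were the same for every list in this and the preceding paragraphs on U-937, except cholesterol synthesis (16 higher).

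The remaining lists did not pass in U-937. The adjusted p was 0.0983 for mast cell, basophil and eosinophil genes (1 higher and 2 lower of 7, or 0 and 2 adjusted over the list alone), 0.160 for immediate-early genes (7 and 2 of 17), 0.319 for genes of the mitochondrial genome (3 and 3 of 13, or 3 and 2 adjusted over the list alone), 0.362 for stroma and endothelium (1 and 0 of 4), 0.475 for plasma cells (0 and 2 of 3), 0.487 for NK cells (2 and 1 of 3), 0.635 for B cells (1 and 2 of 9), 0.776 for the drug targets and their partners (6 and 9 of 19) and 0.970 for genes associated with the RUNX1-RUNX1T1 fusion (2 and 2 of 9). Fewer than 3 genes were tested for the erythroid, megakaryocyte and T-cell lists.

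In SKNO-1, ATRA+TCP raised retinoid targets, antigen presentation genes of both MHC classes and interferon-stimulated genes, and lowered most cholesterol synthesis genes. As lists these passed with the preset correlation, and 0 of 30 lists passed with an estimated correlation. ITGAM went from 0.925 ± 0.273 to 18.8 ± 0.250 CPM (n = 2 per group, log2 change 4.34 ± 0.18, adjusted p = 2.16e-11). CYP26A1 went from 0.0318 ± 0.0450 to 17 ± 0.863 CPM, 531 times higher (95% counting interval 147 to 4393). CST7, an inhibitor of cysteine proteases in granules, fell by 5.69 ± 0.13 on the log2 scale. Of 16390 tested genes, 5474 passed, 2783 higher and 2691 lower, and 1269 of them changed at least 2-fold (872 higher, 397 lower). Without control replicate 2 the number lower was 1754.

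Other large increases in SKNO-1 were in PALLD, an actin-binding protein gene with 0 counts in control (at least 108-fold higher), DHRS3 (1344 times higher, counting interval 459 to 6518), LRRC32, which tethers latent TGF-beta at the cell surface (410 times, 140 to 1993), and HNRNPLL (287 times, 97.7 to 1392). HIC1 rose by 7.56 ± 0.13 on the log2 scale, THBD, the thrombomodulin gene, by 6.79 ± 0.21 and FCGR2B, an inhibitory Fc receptor gene whose counts are uncertain because of its near-identical neighbour FCGR2C, by 6.90 ± 0.17. The potassium channel gene KCNH1 fell by 5.53 ± 0.26, the phosphodiesterase gene PDE9A by 3.93 ± 0.19, SERINC2 by 3.33 ± 0.22 and CYTL1 by 3.17 ± 0.08. The mast cell protease gene CPA3 was at -3.25 ± 0.28, PRG2, which encodes the eosinophil major basic protein, at -3.11 ± 0.10 and the ribonuclease gene RNASE2 at -3.00 ± 0.13. The mast cell, basophil and eosinophil list went both ways, 5 higher and 4 lower of 13 (median 0.12, with the test leaning lower, adjusted p = 0.902). CD86 rose by 1.76 ± 0.20, GFI1 by 0.56 ± 0.06 and RARA by 0.41 ± 0.11 (adjusted p = 0.0148), and RXRA fell by 0.35 ± 0.10 (adjusted p = 0.0122). KDM1A was at -0.06 ± 0.05 (adjusted p = 0.398).

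In SKNO-1, 12 of 30 lists passed, 9 higher and 3 lower. All 11 MHC class I genes rose (median 0.92, adjusted p = 1.06e-09, and adjusted p = 0.0676 with an estimated correlation), with the immunoproteasome subunit PSMB9 at 4.06 ± 0.23 and HLA-B at 2.45 ± 0.08. All 7 MHC class II genes rose (median 0.86, adjusted p = 0.000319, and adjusted p = 0.174 with an estimated correlation). HLA-DPA1 was at 1.51 ± 0.18, CD74 at 0.65 ± 0.06, HLA-DRA at 0.50 ± 0.08 and their transcriptional activator CIITA at 0.60 ± 0.10. Interferon-stimulated genes rose in 20 of 28 cases (21 higher and 1 lower adjusted over the list alone, median 0.58, adjusted p = 2.25e-08), with BST2 at 2.59 ± 0.13, IFIT2 at 2.53 ± 0.14, DDX60 at 2.41 ± 0.12 and IFIT3 at 2.07 ± 0.11. LSD1-responsive genes rose in 10 and fell in 1 of 13 (median 1.76, adjusted p = 3.95e-07), with the myeloid transcription factor CEBPA at 2.37 ± 0.08 and LYZ at 1.05 ± 0.07. With an estimated correlation, both of these lists had an adjusted p = 0.122. Retinoid targets rose in 11 and fell in 4 of 18 cases (12 and 4 adjusted over the list alone, median 1.41, adjusted p = 2.91e-05, and adjusted p = 0.117 with an estimated correlation), with the ubiquitin ligase subunit ASB2 at 5.60 ± 0.12. Monocyte and macrophage genes rose in 10 and fell in 2 of 17 cases (11 and 2 adjusted over the list alone, median 0.68, adjusted p = 0.000198, and adjusted p = 0.123 with an estimated correlation). The proteoglycan VCAN was at 3.17 ± 0.22 and the receptor CSF1R at 2.73 ± 0.24.

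Inflammation genes rose in 9 and fell in 2 of 17 cases (9 and 3 adjusted over the list alone, median 0.47, adjusted p = 0.00154), with the adhesion receptor ICAM1 at 1.92 ± 0.07. TGF-beta response genes rose in 7 and fell in 1 of 14 (median 0.29, adjusted p = 0.00451), with THBS1 at 5.69 ± 0.09 and ID3 at 3.79 ± 0.23. With an estimated correlation, both had an adjusted p = 0.234. Stem and progenitor genes rose in 7 of 13 cases (median 0.21, adjusted p = 0.0161, and adjusted p = 0.274 with an estimated correlation), with CD200 at 1.71 ± 0.08 and the transcription factor ERG at 0.76 ± 0.06. Cholesterol synthesis genes fell in 16 of 20 cases (16 lower and 1 higher adjusted over the list alone, median -0.36, adjusted p = 2.07e-08, and adjusted p = 0.170 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -1.04 ± 0.06. Genes of the mitochondrial genome fell in 5 of 13 cases (10 adjusted over the list alone, median -0.62, adjusted p = 0.000164, and adjusted p = 0.244 with an estimated correlation). Mitosis genes fell in 9 of 23 cases (11 adjusted over the list alone, median -0.15, adjusted p = 0.00266, and adjusted p = 0.706 with an estimated correlation). Granulocyte genes went both ways, 5 higher and 4 lower of 9 (median 0.60, with the test leaning lower, adjusted p = 0.901), with the G-CSF receptor CSF3R at -2.41 ± 0.07 and SRGN of the primary granule list at 1.82 ± 0.08. The megakaryocyte and T-cell lists, with 4 genes each, did not pass (adjusted p = 0.748 for both).

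**Figure D2:**
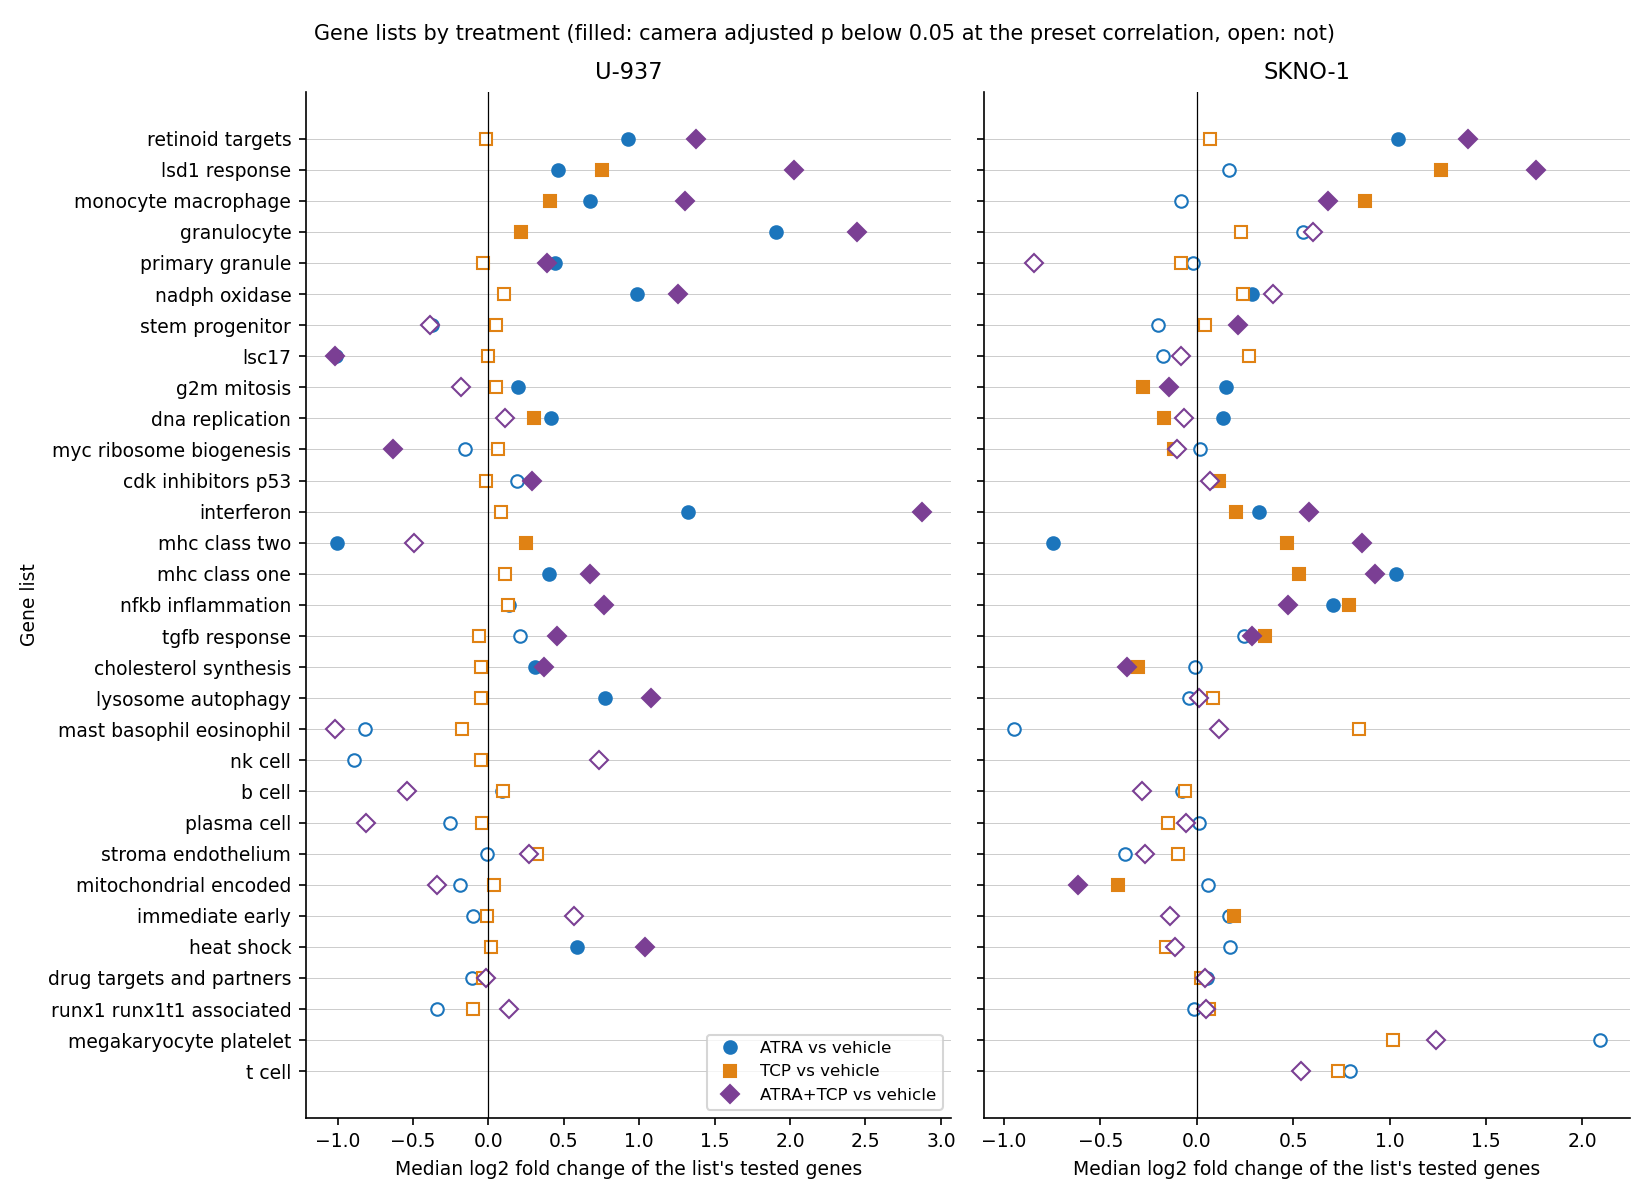
Median log2 change (horizontal axis) of each fixed gene list (vertical axis) in U-937 (left) and SKNO-1 (right), with a point for ATRA, TCP and ATRA+TCP, each against vehicle; filled points passed camera with its preset correlation, and open points did not. The interferon list sits at 2.87 with ATRA+TCP in U-937 and at 0.58 in SKNO-1, and the MHC class II list at -0.49 and 0.86.

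ATRA alone accounted for large retinoid and granulocyte changes in U-937. TGM2 reached 77 ± 8.44 CPM (log2 change 9.33 ± 0.21), RARB was at least 183-fold higher, ARL14EPL 633 times higher (counting interval 113 to 25036) and DAAM2, a Wnt signalling gene, rose by 7.67 ± 0.14. NRXN3 fell by 4.72 ± 0.16, RIC3, a chaperone of acetylcholine receptors, by 4.55 ± 0.19, PDYN by 4.24 ± 0.22 and the cannabinoid receptor gene CNR2 by 3.38 ± 0.28. ITGAM rose by 2.04 ± 0.10 and CD86 by 2.05 ± 0.22. RXRA fell by 0.76 ± 0.13 and RARA by 0.36 ± 0.11 (adjusted p = 0.00956). KDM1A was at -0.12 ± 0.08 (adjusted p = 0.186). Of 31 interferon genes, 26 rose and 2 fell (median 1.33, adjusted p = 1.05e-10), and of 16 granulocyte genes 15 rose (15 higher and 1 lower adjusted over the list alone, median 1.91, adjusted p = 1.29e-08). Both had an adjusted p = 0.241 with an estimated correlation. MHC class II genes fell in 5 of 7 cases (median -1.0, adjusted p = 0.00317, and adjusted p = 0.327 with an estimated correlation), with HLA-DRA at -1.64 ± 0.21 and CIITA at -3.07 ± 0.18. DNA replication genes rose in 18 and fell in 1 of 24 cases (median 0.41, adjusted p = 6.54e-05, and adjusted p = 0.365 with an estimated correlation). In total 8328 genes passed, 4360 higher and 3968 lower, 2414 of them by at least 2-fold, and 15 of 29 lists passed, 13 higher and 2 lower.

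TCP alone changed fewer genes in U-937, mainly upward. KCTD12, an auxiliary subunit of GABA-B receptors, rose by 3.80 ± 0.13, LILRA6, whose counts are uncertain because of near-identical relatives, by 2.47 ± 0.21, GLIPR1 by 2.12 ± 0.13 and the serine protease FAP by 2.03 ± 0.15. NRXN3 fell by 1.18 ± 0.12, the succinate receptor gene SUCNR1 by 1.14 ± 0.12, the TNF receptor family gene TNFRSF14 by 1.12 ± 0.11 and the transporter gene SLCO4C1 by 1.10 ± 0.19. CD86 rose by 1.80 ± 0.22, ITGAM by 1.29 ± 0.10 and GFI1 by 0.48 ± 0.08, and KDM1A was at -0.01 ± 0.08 (adjusted p = 0.994). LSD1-responsive genes rose in 10 of 13 cases (10 higher and 1 lower adjusted over the list alone, median 0.75, adjusted p = 1.05e-17, and adjusted p = 0.0714 with an estimated correlation). Monocyte and macrophage genes rose in 9 of 22 cases (14 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p = 1.72e-11, and adjusted p = 0.107 with an estimated correlation). DNA replication genes rose in 7 of 24 cases (17 adjusted over the list alone, median 0.30, adjusted p = 8.82e-16, and adjusted p = 0.286 with an estimated correlation). In total 428 genes passed, 329 higher and 99 lower, and 148 by at least 2-fold. The count was 211 without control replicate 1, 222 without control replicate 2, 232 without TCP replicate 1 and 260 without TCP replicate 2, and the 2 TCP replicates carry different dose labels.

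In SKNO-1, ATRA alone raised CYP26A1 to 152 ± 9.13 CPM, 4798 times the control level (counting interval 1328 to 39628). DHRS3 was 815 times higher (278 to 3954), and THBS1, which encodes the matrix protein thrombospondin, rose by 8.74 ± 0.09. CPA3 was 346 times lower (61.8 to 13706), CST7 fell by 5.89 ± 0.13, CYTL1 by 4.90 ± 0.11 and the complement receptor gene C5AR2 by 4.5 ± 0.20. CD86 fell by 2.37 ± 0.33, ITGAM rose by 0.67 ± 0.24 (adjusted p = 0.0486), RARA rose by 0.90 ± 0.11 and RXRA fell by 0.80 ± 0.10. Retinoid targets rose in 12 and fell in 2 of 18 cases (13 and 2 adjusted over the list alone, median 1.04, adjusted p = 2.58e-09, and adjusted p = 0.0649 with an estimated correlation). MHC class II genes fell in 5 of 7 cases (median -0.75, adjusted p = 0.00156, and adjusted p = 0.454 with an estimated correlation), with HLA-DRA at -1.55 ± 0.09. Class I genes rose in 8 and fell in 1 of 11 (8 and 2 adjusted over the list alone, median 1.03, adjusted p = 0.000511, and adjusted p = 0.183 with an estimated correlation). In total 4460 genes passed, 2222 higher and 2238 lower, 1093 by at least 2-fold, and 8 lists passed, 7 higher and 1 lower. Without control replicate 1 the count was 2863, and without ATRA replicate 1 it was 2891.

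TCP alone raised many monocyte and inflammation genes in SKNO-1. GFI1B, a relative of GFI1 that also works with LSD1, was 500 times higher (counting interval 89.3 to 19798), FCGR2B rose by 7.02 ± 0.17, the tetraspanin gene TSPAN7 by 5.31 ± 0.34 and CRYBG1 by 4.35 ± 0.10. CD180, a Toll-like receptor relative, fell by 2.46 ± 0.13, SUCNR1 by 1.61 ± 0.10, KCNH1 by 1.53 ± 0.18, and the prostaglandin receptor gene PTGER2 by 1.24 ± 0.18. ITGAM rose by 2.71 ± 0.19, CD86 by 2.55 ± 0.20, RXRA by 0.66 ± 0.09 and GFI1 by 0.49 ± 0.06. Inflammation genes rose in 12 of 17 cases (12 higher and 2 lower adjusted over the list alone, median 0.79, adjusted p = 4.25e-07), and LSD1-responsive genes rose in 10 and fell in 2 of 13 (median 1.27, adjusted p = 2.60e-06). Monocyte and macrophage genes rose in 11 and fell in 2 of 17 (11 and 3 adjusted over the list alone, median 0.88, or 0.71 with genes near 0 counts at their bound, adjusted p = 0.000286). Cholesterol synthesis genes fell in 16 of 20 cases (17 adjusted over the list alone, median -0.30, adjusted p = 1.41e-09). These 4 lists had an adjusted p = 0.158 with an estimated correlation. Mitosis genes fell in 15 of 23 cases (20 adjusted over the list alone, median -0.28, adjusted p = 2.22e-09, and adjusted p = 0.268 with an estimated correlation). In total 3472 genes passed, 1787 higher and 1685 lower, 566 by at least 2-fold, and 14 lists passed, 9 higher and 5 lower. The count was 1946 without control replicate 1, 1805 without control replicate 2, 2270 without TCP replicate 1 and 1942 without TCP replicate 2.

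**Figure D3:**
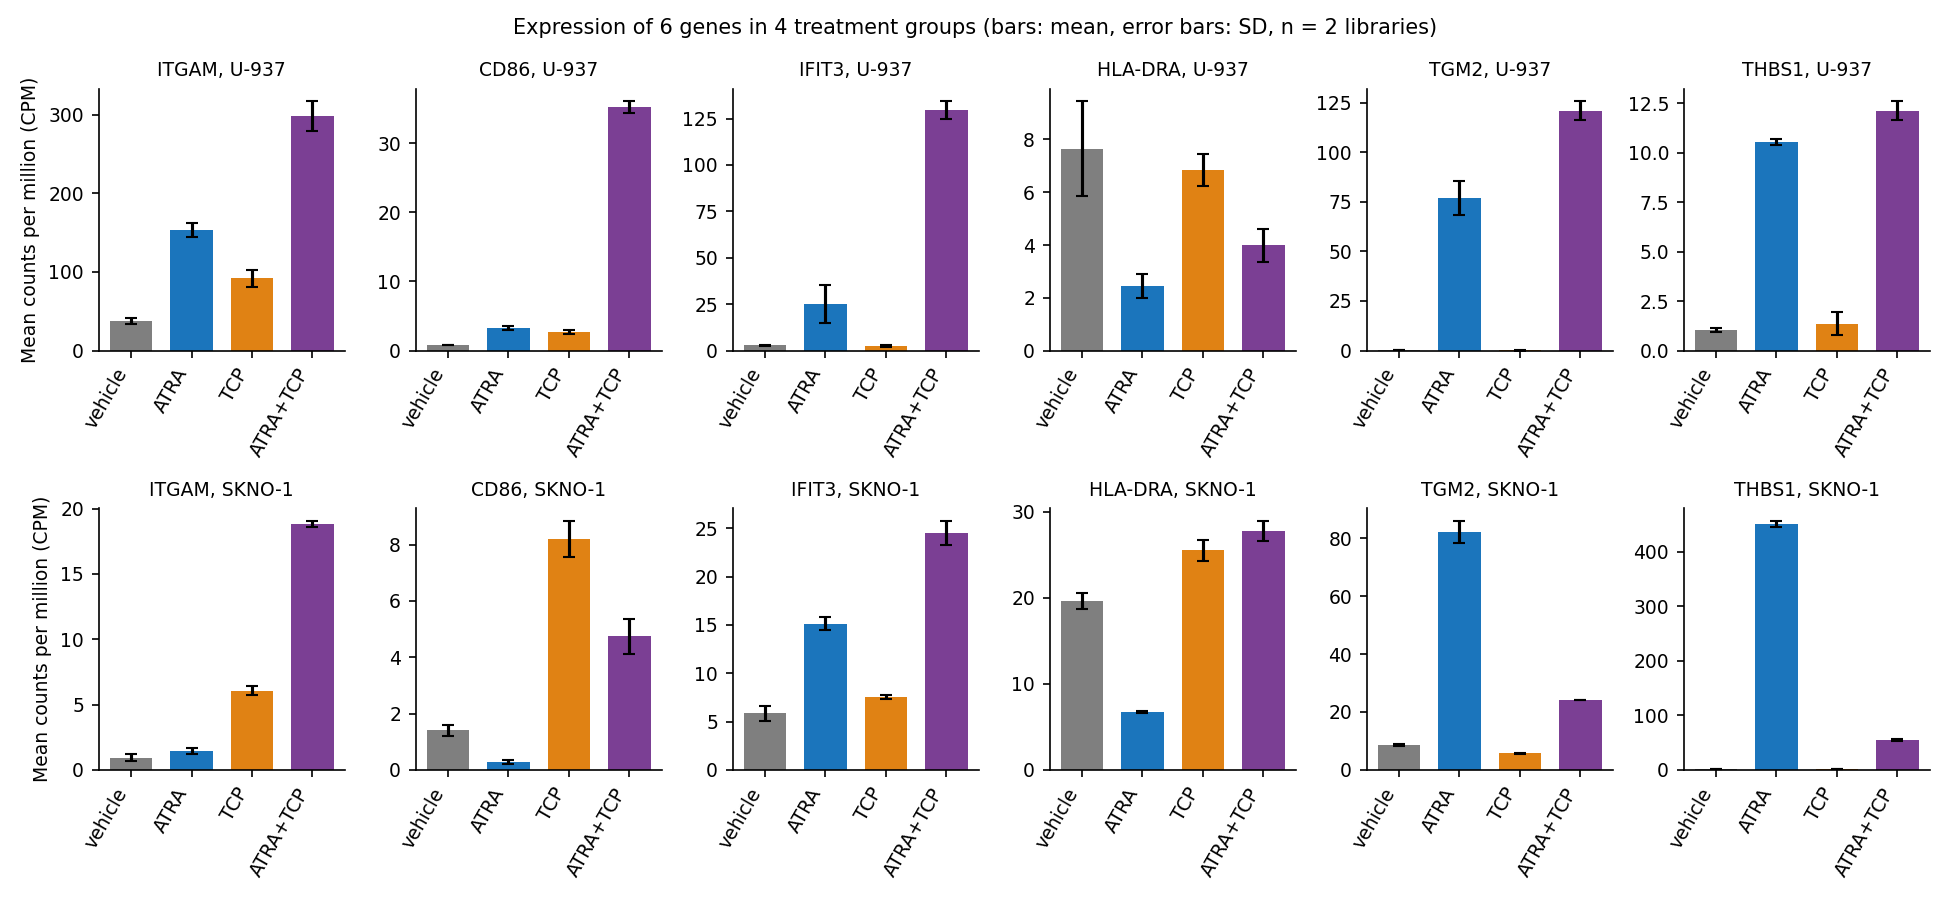
Expression in CPM (vertical axes, starting at 0) of ITGAM, CD86, IFIT3, HLA-DRA, TGM2 and THBS1 in control (vehicle), ATRA, TCP and ATRA+TCP cells of U-937 and SKNO-1; bars are means of 2 libraries, error bars the SD. In U-937, CD86 stood at 3.28 with ATRA, 2.74 with TCP and 35.2 with both; in SKNO-1, THBS1 stood at 451 with ATRA and 54.4 with both.

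Adding TCP to ATRA was tested as ATRA+TCP against ATRA. In U-937 it raised CD86 by a further 3.43 ± 0.14 and ITGAM by 0.96 ± 0.09. It also raised TNFSF15 (5.25 ± 0.26), CNR2 (4.71 ± 0.26), LILRB3, an inhibitory receptor gene with near-identical relatives (3.85 ± 0.21), and the anion exchanger SLC26A11 (3.85 ± 0.22). SPTB fell by 2.88 ± 0.25, the adhesion gene FERMT1 by 2.12 ± 0.15, the amino acid transaminase gene BCAT1 by 1.93 ± 0.12 and the calcium channel gene CACNA2D3 by 1.90 ± 0.20. Interferon genes rose in 27 of 31 cases (28 adjusted over the list alone, median 1.45, adjusted p = 1.75e-23), and monocyte and macrophage genes rose in 18 and fell in 1 of 22 (19 and 1 adjusted over the list alone, median 1.0, adjusted p = 3.41e-11). Both had an adjusted p = 0.0753 with an estimated correlation. All 7 MHC class II genes rose (median 1.19, adjusted p = 5.27e-06, and adjusted p = 0.182 with an estimated correlation), with CIITA at 1.19 ± 0.20. Mitosis genes fell in 18 of 23 cases (20 adjusted over the list alone, median -0.41, adjusted p = 1.32e-07, and adjusted p = 0.229 with an estimated correlation) and MYC and ribosome biogenesis genes in 18 of 22 (median -0.40, adjusted p = 7.83e-09, and adjusted p = 0.193 with an estimated correlation). The test passed 5243 genes, 2581 higher and 2662 lower, and 853 by at least 2-fold. Without ATRA replicate 1 the count was 3490, of which 1483 were lower, and without ATRA+TCP replicate 1 the number lower was 1672.

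In SKNO-1, adding TCP to ATRA raised ITGAM by 3.67 ± 0.17 and CD86 by 4.13 ± 0.28. It raised FCGR2B by 7.64 ± 0.20, WFDC1, a protease inhibitor relative, by 7.28 ± 0.28, the sulfotransferase gene SULT1C2 by 6.41 ± 0.34 and the sphingosine phosphate receptor gene S1PR1 by 6.28 ± 0.28. CD180 fell by 3.37 ± 0.09, ZNF618 by 3.36 ± 0.31, CYP26A1 by 3.16 ± 0.09 and THBS1 by 3.05 ± 0.06. All 7 MHC class II genes rose (median 2.05, adjusted p = 1.75e-07), stem and progenitor genes rose in 9 of 13 cases (median 0.57, adjusted p = 3.26e-06) and cholesterol synthesis genes fell in 16 of 20 (18 adjusted over the list alone, median -0.40, adjusted p = 3.11e-11). These 3 lists had an adjusted p = 0.153 with an estimated correlation. The test passed 4938 genes, 2567 higher and 2371 lower, and 941 by at least 2-fold. Without ATRA replicate 1 or 2 the number lower was 1488 or 1397.

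Adding ATRA to TCP was tested as ATRA+TCP against TCP. In U-937, TGM2 rose by 10.19 ± 0.21, RARB was at least 97.6-fold higher, VSIG4 570 times higher (counting interval 102 to 22558) and DAAM2 rose by 8.04 ± 0.15. PWAR5 was at least 101-fold lower, PDYN fell by 5.10 ± 0.27, NRXN3 by 4.95 ± 0.20 and GNAL by 4.14 ± 0.30. CD86 rose by 3.68 ± 0.15 and ITGAM by 1.70 ± 0.09. Of the lists, interferon (29 higher of 31, median 2.79, adjusted p = 1.54e-17), granulocyte (15 of 16, median 2.03, adjusted p = 2.21e-09) and lysosome and autophagy genes (20 of 20, median 1.13, adjusted p = 1.69e-12) rose, each with an adjusted p = 0.155 with an estimated correlation. In SKNO-1, DHRS3 was 1805 times higher (499 to 14913), CYP26A1 476 times (131 to 3935), PALLD 293 times (52.2 to 11604) and HNRNPLL 257 times (87.6 to 1247). CEACAM6, a granulocyte adhesion molecule, fell by 6.29 ± 0.31, CST7 by 5.59 ± 0.13, CPA3 by 4.95 ± 0.26 and the interleukin receptor gene IL1R1 by 4.30 ± 0.18. ITGAM rose by 1.63 ± 0.14 and CD86 fell by 0.79 ± 0.17 (adjusted p = 0.00321). Retinoid targets rose in 10 and fell in 3 of 18 cases (11 and 3 adjusted over the list alone, median 0.97, adjusted p = 4.99e-06, and adjusted p = 0.0788 with an estimated correlation). The test passed 9704 genes in U-937 (4842 higher, 4862 lower, 3316 by at least 2-fold) and 3243 in SKNO-1 (1619 higher, 1624 lower, 877 by at least 2-fold). In SKNO-1 the number lower was 1028 without TCP replicate 2.

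**Figure D4:**
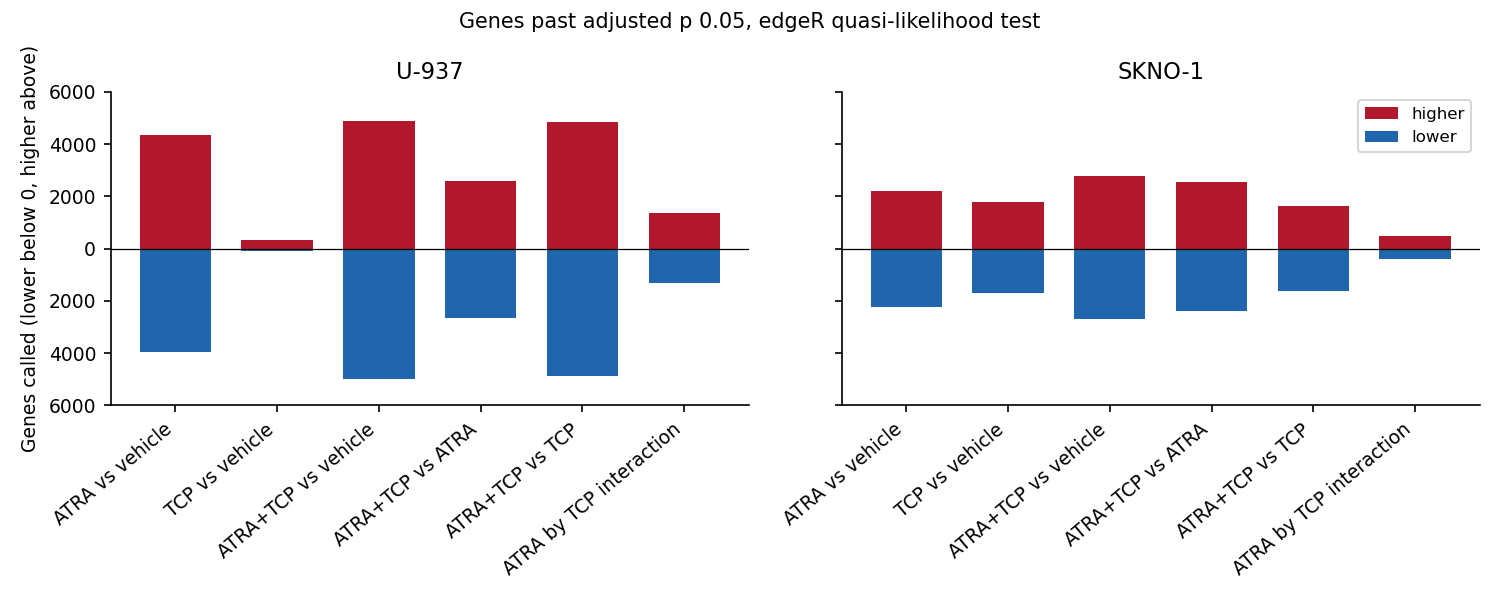
Number of genes that passed the adjusted threshold (vertical axis, starting at 0), higher and lower, for the 6 comparisons within U-937 (left) and SKNO-1 (right); each bar is a count from 1 test, so there are no error bars. TCP alone passed 428 genes in U-937 and 3472 in SKNO-1, and ATRA+TCP passed 9885 and 5474.

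The interaction test asked whether the combined log2 change differed from the sum of the single-drug changes. In U-937, CD86 lay above that sum by 1.63 ± 0.29 (adjusted p = 0.00109), the guidance factor gene SEMA3C by 4.03 ± 0.49 and CNR2 by 3.52 ± 0.34. The prostaglandin synthase gene PTGES and the metalloprotease gene ADAM19 also passed above it, with fitted values of 3.92 and 3.53 that depend on the prior count, since they had 0.0393 and 0.0591 CPM with TCP. SPTB was below it at -2.35 ± 0.30, FERMT1 at -2.09 ± 0.19 and GNAL at -1.87 ± 0.42. For PWAR5, with 0 counts under the combination, the fitted -8.24 depends on the prior count and is no bound. ITGAM did not pass, at -0.34 ± 0.13 (adjusted p = 0.0881). Interferon genes lay above the sum in 21 of 31 cases (24 adjusted over the list alone, median 1.29, adjusted p = 1.22e-23). Below it were DNA replication genes in 17 of 24 cases (21 adjusted over the list alone, median -0.54, adjusted p = 7.65e-13) and MYC and ribosome biogenesis genes in 14 of 22 (17 adjusted over the list alone, median -0.48, adjusted p = 6.52e-11). These 3 lists had an adjusted p = 0.207 with an estimated correlation. In total 2666 genes passed, 1365 above and 1301 below the sum, and 474 by at least 2-fold. The count was 995 without control replicate 2, 1215 without TCP replicate 1 and 1699 without ATRA replicate 1.

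In SKNO-1, WFDC1 (3.68 ± 0.45), S1PR1 (2.65 ± 0.48), the transcriptional regulator ARID5B (2.26 ± 0.20) and CYTL1 (2.15 ± 0.15) lay above the sum, as did CD86 (1.58 ± 0.38, adjusted p = 0.0221). This did not place them all above each single drug. CD86 stood at 4.75 CPM with both drugs and 8.21 CPM with TCP alone. The same levels were 11.7 and 25.2 CPM for WFDC1, 6.62 and 24.2 for ARID5B, and 4.797 and 32.2 for CYTL1. With both drugs ARID5B and CYTL1 also lay below control (13.5 and 43.2 CPM). S1PR1 lay above TCP alone (8.62 against 5.75 CPM). All of these genes had a lower mean with ATRA alone than in control. THBS1 (-3.41 ± 0.18), the leukotriene synthesis gene ALOX5AP (-2.49 ± 0.29), the adhesion gene MPZL2 (-2.38 ± 0.25) and the sodium channel subunit gene SCN4B (-2.24 ± 0.25) lay below the sum, and RARA was at -0.65 ± 0.16 (adjusted p = 0.0371). ITGAM did not pass (0.96 ± 0.28, adjusted p = 0.0609), nor did CYP26A1, which had few counts in control and with TCP (adjusted p = 0.235). MHC class II genes lay above the sum in 5 of 7 cases (6 adjusted over the list alone, median 0.91, adjusted p = 1.04e-07), with HLA-DRA at 1.67 ± 0.12. Below it lay 6 inflammation genes, with 1 above, of 17 (7 and 1 adjusted over the list alone, median -0.76, adjusted p = 1.04e-07), among them the NF-kB inhibitor TNFAIP3 at -1.48 ± 0.09. So did 6 of 18 retinoid targets (median -0.51, adjusted p = 0.000117). These 3 lists had an adjusted p = 0.151 with an estimated correlation. In total 885 genes passed, 493 above and 392 below the sum, and 190 by at least 2-fold. Without control replicate 1 or 2 the count was 458 or 557, without ATRA replicate 1 it was 456, without TCP replicate 2 it was 581 and without ATRA+TCP replicate 1 it was 1342.

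The responses of the lines to ATRA+TCP were then compared. Of 14588 genes tested in both, 1216 were higher in both lines (740 if the calls were independent) and 923 lower in both (708 if independent). A further 702 were higher in U-937 and lower in SKNO-1, and 513 the reverse, with 729 and 719 if independent. Counting changes of at least 2-fold in each line, the numbers were 277 higher in both (54.4 if independent) and 62 lower in both (22.7), with 45 higher in U-937 and lower in SKNO-1 (20.6) and 39 the reverse (59.8). Across genes, which are not independent replicates, the log2 changes correlated with r = 0.29. The genes named next were chosen after their values were seen, from the largest changes. HNRNPLL (8.19 ± 0.19 in U-937), HIC1 (6.83 in U-937 and 7.56 in SKNO-1) and DHRS3 (5.26 in U-937) rose in both, HNRNPLL and DHRS3 from 3 counts each in SKNO-1 control, and the kinase gene AK5 (-4.96 and -2.51) and the receptor gene RET (-4.56 and -1.98) fell in both. CD36, a scavenger receptor, rose by 5.38 ± 0.11 in U-937 and had 0 counts in SKNO-1 under the combination. The mast cell protease gene TPSAB1, which has near-identical copies, changed by -2.34 ± 0.11 in U-937 and by 2.78 ± 0.91 in SKNO-1, where the SE was wide.

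The difference between the lines was tested gene by gene, as SKNO-1 minus U-937, and 7384 of 18963 genes passed, 3813 above and 3571 below 0 (2835 by at least 2-fold). CD86 rose less in SKNO-1 (difference -3.71 ± 0.28, adjusted p = 3.82e-10) and ITGAM rose more (1.36 ± 0.21, adjusted p = 2.32e-05). KDM1A (0.21 ± 0.09, adjusted p = 0.0868), RARA (0.15 ± 0.16, adjusted p = 0.533) and GFI1 (0.23 ± 0.10, adjusted p = 0.0730) did not pass. Interferon genes had the lowest p by camera with the preset correlation, with 23 of 31 lower and 2 higher (median -2.09, adjusted p = 7.86e-12, and adjusted p = 0.0538 with an estimated correlation). Lysosome genes followed, with 18 of 21 lower and 1 higher (median -1.14, adjusted p = 8.71e-11, and adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis genes were lower in 17 of 20 cases (median -0.81, adjusted p = 1.06e-09, and adjusted p = 0.105 with an estimated correlation), and granulocyte genes in 10 of 17, with 1 higher (median -2.62, adjusted p = 6.22e-08, and adjusted p = 0.0533 with an estimated correlation). MYC and ribosome biogenesis genes were higher in 15 of 22 cases (16 adjusted over the list alone, median 0.55, adjusted p = 7.40e-06, and adjusted p = 0.295 with an estimated correlation). The LSD1-responsive list did not pass (3 higher and 6 lower of 14, adjusted p = 0.101), nor did retinoid targets (7 and 6 of 22, adjusted p = 0.759).

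In patients, treated against baseline asked what changed in CD34-positive marrow cells during treatment with both drugs. The genes with the lowest p toward higher values on treatment were the antisense gene BAALC-AS1 (log2 difference 2.20 ± 0.59, with the strand setting of the counting not given), the netrin receptor gene UNC5C (3.91 ± 1.28) and the olfactory receptor genes OR2C3 (5.11 ± 1.76) and OR10A2 (3.46 ± 1.25). Toward lower values they were the protease inhibitor gene SERPINA1 (1 count against 225, 147 times lower with a counting interval of 26.1 to 5827), AIG1 (-4.03 ± 1.45), the mitochondrial ribosomal RNA gene MT-RNR1 (-1.63 ± 0.60) and the neutrophil protease gene PRTN3 (-3.28 ± 1.23). None of these passed (adjusted p = 1 for each). SERPINA1 had 0 counts in 4 of 8 baseline and 5 of 6 treated libraries, and OR2C3 in 7 of 8 and 3 of 6. The counting interval does not cover the spread between patients. ITGAM was at 38.6 ± 51.7 CPM on treatment and 45.2 ± 32.5 CPM at baseline (mean ± SD, 6 and 8 libraries), and its log2 difference was 0.16 ± 1.03, although its mean was lower on treatment and the sign changed under other settings. KDM1A was at 0.28 ± 0.76, RARA at -0.53 ± 1.10, GFI1 at -1.55 ± 1.29 and RXRA at -1.09 ± 1.31. CD86 and CYP26A1 were too low to be tested. By edgeR, 0 of 12247 genes passed, with 152 at an unadjusted p below 0.05, where other splits of the libraries gave a median of 245. DESeq2 also passed 0 genes, with 287 at that unadjusted level, and limma-voom 0, with 515. The treated and baseline tables were deposited separately, so a difference in handling cannot be told apart from treatment. In simulated data of this spread edgeR recovered 0 and DESeq2 11 of 58 genes with a 4-fold change, so most changes of that size would have been missed.

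As groups, 5 of 32 lists passed camera between treated and baseline, all toward lower values, with no member passing by itself over all genes or adjusted over the list alone. They were inflammation genes (13 tested, median -0.72, adjusted p = 0.0116), LSD1-responsive genes (12, median -0.98), mast cell, basophil and eosinophil genes (5, median -1.20) and genes of the mitochondrial genome (13, median -0.89), each with an adjusted p = 0.0164, and primary granule genes (9, median -1.40, adjusted p = 0.0286). Each had an adjusted p = 0.898 with an estimated correlation. Among their members, CXCL8 was at -2.93 ± 1.26, LYZ at -1.57 ± 0.78, TPSAB1 at -5.26 ± 2.11, AZU1, a granule protein gene, at -2.92 ± 1.48 (although its mean was 34.1 CPM at baseline and 32.4 CPM on treatment) and MT-CO1 at -1.09 ± 0.49. The mean of ELANE, another granule gene, was 8.69 CPM at baseline and 25.6 CPM on treatment. Among LSD1-responsive genes, the means of GFI1B (34.1 and 64.7 CPM) and IRF8 (10.8 and 25.8 CPM) were also higher on treatment. So was that of KIT (150 and 168 CPM) in the mast cell, basophil and eosinophil list. The means of the other tested members of these lists were lower on treatment. The median share of mitochondrial counts was 4.18% at baseline and 4.74% on treatment, and 1 baseline library held 30.7%, so the call for mitochondrial genes may rest on that library, which was not tested. The median over all tested genes was -0.18. Erythroid genes lay higher without passing (7 tested, median 1.5, adjusted p = 0.136), with the haemoglobin genes HBA2 at 3.53 ± 1.29 and HBB at 2.01 ± 1.41. Interferon genes (27 tested, median -0.08, adjusted p = 0.645) and MHC class II genes (11 tested, median -0.09, adjusted p = 0.563) did not pass. The genes that rose in both cell lines, of which 967 were tested here, lay lower on treatment (median -0.36, 30.4% above 0 against 40.4% of all genes, adjusted p = 0.0194). This camera call was lost with an estimated correlation (adjusted p = 0.814) and with lists of genes changed at least 2-fold in both lines (adjusted p = 0.131). It was also lost with the patient as a block over the 3 pairs (adjusted p = 0.980). The genes that fell in both lines did not pass (718 tested, median -0.26, 34.3% above 0, adjusted p = 0.203).

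Baseline AML and MDS were compared as the other group label of the patient samples, with 6 libraries against 2. Genes of the mitochondrial genome were lower in AML (13 of 13 adjusted over the list alone and 0 over all genes, median -2.14, adjusted p = 3.77e-17, and adjusted p = 0.850 with an estimated correlation), with MT-ND4L at -3.56 ± 0.77 and MT-ND2 at -2.48 ± 0.67. Their direction rests on 1 MDS library, without which MT-ND4L was at 1.10 and MT-ND2 at 0.26. Toward higher values in AML, the lowest p belonged to C1QTNF4 (2026 counts against 1, 708 times higher with a counting interval of 127 to 27959, adjusted p = 0.0749), the lymphoid and leukaemic surface receptor CD96 (at least 72.5-fold, adjusted p = 0.395), CEBPA (4.31 ± 1.34, adjusted p = 0.730) and HRNR, an epidermal protein gene (at least 48.0-fold, adjusted p = 0.819). CRHBP (-5.00 ± 1.08, adjusted p = 0.0539) and the interleukin-33 receptor gene IL1RL1 (-5.73 ± 1.38, adjusted p = 0.104) were lower, and without the other MDS library they were at 1.47 and 5.30. ITGAM was at 2.80 ± 1.79, GFI1 at 2.66 ± 2.14, KDM1A at -0.69 ± 1.18, RARA at 0.74 ± 1.67 and RXRA at 0.35 ± 1.81, each with an adjusted p of 1.00. Granulocyte (4 tested, median 2.35) and DNA replication genes (22, median 1.56) passed as higher and immediate-early (17, median -0.66) and heat shock genes (10, median -0.42) as lower, each with an adjusted p = 0.0264, and adjusted p = 0.850 with an estimated correlation. By edgeR, 0 of 13524 genes passed, with 391 at an unadjusted p below 0.05, and DESeq2 passed 0 with 594 at that level.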

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

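Of the tests in this part, the relation to genes detected and the comparison of standard errors were chosen after the results were seen.

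In the between-line comparison, the response to ATRA+TCP differed for 7384 genes, tested as SKNO-1 minus U-937. Fitted log2 differences where a group has few or 0 counts depend on the prior count and are no bounds. They were largest toward SKNO-1 for SULT1C2 (10.63), PWAR5 (9.56), CYP26A1 (8.77) and IGLL1, a surrogate light chain gene of B-cell precursors (7.74), and toward U-937 for TNFSF15 (-13.84), the calprotectin genes S100A9 (-12.68) and S100A8 (-12.14), and CD36 (-11.92). As levels under ATRA+TCP, SULT1C2 was at least 117-fold, PWAR5 at least 96.2-fold and IGLL1 at least 1037-fold higher in SKNO-1, while TNFSF15 was at least 285-fold, S100A9 at least 2059-fold, S100A8 at least 248-fold and CD36 at least 13108-fold higher in U-937.

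The lists that passed toward U-937 were interferon (median -2.09), granulocyte (-2.62), primary granule (-1.66, 8 of 11 lower, adjusted p = 7.40e-06, and adjusted p = 0.147 with an estimated correlation), lysosome and autophagy (-1.14), heat shock (-0.87, 8 lower and 1 higher of 11, adjusted p = 0.000446, and adjusted p = 0.204 with an estimated correlation), cholesterol synthesis (-0.81), CDK inhibition and p53 (-0.61, 8 lower and 1 higher of 17, adjusted p = 0.0496, and adjusted p = 0.348 with an estimated correlation), monocyte and macrophage (-0.53, 9 lower and 1 higher of 26, adjusted p = 0.00237, and adjusted p = 0.175 with an estimated correlation), NADPH oxidase (-0.41, 4 of 6 lower, adjusted p = 0.000269, and adjusted p = 0.151 with an estimated correlation) and DNA replication (-0.18, 9 lower and 2 higher of 24, adjusted p = 0.0453, and adjusted p = 0.562 with an estimated correlation). Toward SKNO-1 they were MYC and ribosome biogenesis (0.55) and MHC class I (0.46, 6 higher and 1 lower of 12, adjusted p = 0.0182, and adjusted p = 0.175 with an estimated correlation). Adjusted over the list alone, the lower and higher counts were 8 and 2 for heat shock, 9 and 1 for CDK inhibition and p53, 10 and 3 for monocyte and macrophage and 1 and 7 for MHC class I; the other counts in this paragraph were the same.

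A first pattern is the larger interferon response in U-937, where 23 of 31 genes differed toward U-937. Scaling to library totals alone kept 0.914 of the median difference (-1.91 against -2.09), which argues against the TMM factors as its cause. Both settings scale a library by 1 factor, so other kinds of normalization were not tested. With the libraries thinned to equal totals, 0.971 of it was kept (median -2.03), so the unequal totals of these libraries do not account for it. Totals of the 16 libraries ran only from 21750220 to 37722180. The thinning was therefore mild and does not test lower depth. A difference between the lines in interferon signalling is a candidate explanation that was not tested.

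A second pattern is the smaller number of genes called with TCP in U-937 (428) than in SKNO-1 (3472). If the 1 uM label of U-937 TCP replicate 2 had lowered its response, that replicate would lie below the other one. Over 403 genes that TCP changed at least 2-fold in SKNO-1, its mean response in that direction was 0.409 ± 0.0355 (SE over genes) against 0.370 ± 0.0352 in replicate 1. The ratio was 1.11, so replicate 2 did not lie below replicate 1 over these genes. With 1 library per dose label, and with genes that are not replicates, this cannot tell which dose was given. A wider spread between U-937 libraries is argued against by the median standard errors, 0.114 in U-937 and 0.0988 in SKNO-1, a ratio of 1.15. In SKNO-1 the mean absolute log2 change of the same 403 genes was 1.87. They were chosen for their change in that line, so the sizes are not an even comparison. A weaker response of U-937 to TCP may remain, and was not tested with other doses.

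The last pattern is the wide spread between patient libraries with 0 genes called by edgeR (152 at an unadjusted p below 0.05, and 0 called by DESeq2). Low totals over all genes would not by themselves have hidden an effect of the size seen in U-937, since its libraries thinned to patient totals still called 3397 genes. The patient totals include ribosomal RNA loci (9.08% to 49.0% of counts), which took at most 0.00462% in U-937. The thinned libraries therefore kept more counts for other genes, and the depth of patient libraries outside these loci was not tested. The first principal component (41.1% of the variance) parted 6 libraries with 7455 to 11803 genes detected from 8 with 15303 to 20254, and tracked genes detected within the 6 (r = 0.931, exact permutation p = 0.00833, adjusted over 4 relations 0.0333; rho 0.886, exact p = 0.0333, adjusted 0.0667; r = 0.854 without the 2 farthest libraries) but not within the 8 (r = -0.306, exact p = 0.478, adjusted 0.478; rho -0.476, exact p = 0.243, adjusted 0.324; r = -0.549 without the 2 farthest). Genes detected were counted here without the 556 genes left out in patients. The 6 libraries also had the lowest totals, 397881 to 798079 counts, against 1151966 to 2728942 in the 8. Library complexity therefore stays open and cannot be told apart from library total or from differences between patients. Of the 6 libraries 3 were treated, and of the 8 also 3.

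Chance cannot be excluded for the list results in patients. Over 100 of the 3003 splits of the 14 libraries, the real one included, 32 gave at least as many lists as the real 5 (highest other 14), and 33 gave a p as low for the genes shared by the lines as the real 0.0194 (lowest other 1.70e-07). With 0 genes called in the real split (highest other 8), the count of genes cannot test chance. The real split parts all 3 patient pairs. Of the other splits, 24 do so too, with at most 2 genes and 5 lists called, and 4 of them gave as many lists.

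Single patient libraries were flagged as apart from their group in 15 of 50 checks. The rate of about 1 in 20 for which the checks were set is not the chance rate here. Several genes had skewed CPM values, and many of the genes flagged had been named for their low p in these same libraries. The count of 15 therefore cannot show whether more libraries stood apart than by chance. For each gene by itself, 1 baseline AML library stood above the others, for OR10A2 at 2.44 CPM, AIG1 at 64.2, MT-RNR1 at 4461, CEBPA at 1303, HRNR at 216 and CRHBP at 91.1 CPM, and 1 below the others for ITGAM at 5.06 CPM. Likewise for each gene by itself, 1 treated AML library stood above the others, for BAALC-AS1 at 6959 CPM, OR10A2 at 15.5, SERPINA1 at 0.554, PRTN3 at 19.6, HRNR at 177, CRHBP at 140.4 and MT-ND2 at 5331 CPM. The SERPINA1 value is 1 count, with 5 of 6 treated libraries at 0. OR10A2 was at 0 in 6 of 8 baseline libraries, so its baseline value is also near the floor. By mitochondrial counts, 1 treated AML library stood above the others at 6.80%. Whether these are the same library was not tested.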

How the results depend on the processing

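Tests on libraries with 1000000 counts or more, and without abundant non-coding and mitochondrial RNA, were chosen after seeing the data. Counts of called genes stayed within 1.5 times under RLE normalization, DESeq2, no filter and the replicate block in the cell lines, except as given here. Of the values followed in the lines, 1596 kept direction and side of the threshold, 47 fell below it, 15 rose above it and 11 changed sign. The 1596 include a few counts of genes differing between or shared by the lines that stayed within 1.5 times. A further 5 values that moved by more than that were such counts and not named genes. For named genes in patients, 411 values kept direction and side of the threshold, 9 rose above it and 16 changed sign. Of list calls 63 were kept and 36 lost. Depth limits the levels that can be seen: 3 counts in a library stood for a median of 2.11 CPM at baseline and 3.29 CPM on treatment in patients, against 0.123 CPM in U-937 and 0.0956 CPM in SKNO-1. Where a value moved, the cause was not tested unless given.

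By construction, the 2-fold minimum left fewer genes: in U-937 3539 for ATRA+TCP, 2414 for ATRA, 148 for TCP, 853 against ATRA, 3316 against TCP and 474 for the interaction; in SKNO-1 1269, 1093, 566, 941, 877 and 190; between the lines 2835; and shared by the lines 339. With DESeq2, TCP lowered 1005 genes in SKNO-1 (1685 by edgeR), and 607 genes fell in both lines (923). With no filter TCP lowered 183 genes in U-937 (99 with it), the SKNO-1 interaction had 1393 genes (759 higher, 634 lower) and treated against baseline 6 (4 higher, 2 lower). RLE gave 1 gene for AML against MDS. With an estimated correlation 0 lists passed by camera in U-937 (16 by the preset), SKNO-1 (12) and patients (5), and the list of genes higher in both lines had an adjusted p = 0.814 in patients, 0.131 as the 2-fold list and 0.980 with the patient as replicate block.

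The replicate block gave 9843 genes for ATRA+TCP in U-937 and 5295 in SKNO-1 and 7310 between the lines. Replicate numbers did not pair the samples (correlations of replicate differences -0.0764 to 0.104). With the 3 patient pairs as block, edgeR called 0 genes and 5 lists passed. Apart from the loss of the list call above, the block moved no count of calls by more than 1.5 times. For ATRA+TCP in U-937, 15 lists passed with the replicate block, against 16 without it.

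Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave in U-937 8053 to 9023 genes for ATRA+TCP (4158 to 4787 higher, 3895 to 4236 lower), 6316 to 8061 for ATRA (3297 to 4327, 3019 to 3734), 211 to 260 for TCP (173 to 201, 31 to 69), 3490 to 5501 against ATRA (2007 to 2873, 1483 to 2628), 8131 to 8845 against TCP (4206 to 4618, 3925 to 4227) and 995 to 3628 for the interaction (546 to 1849, 449 to 1779). In SKNO-1 it gave 3824 to 5253 for ATRA+TCP (2028 to 2849, 1754 to 2404), 2863 to 3312 for ATRA (1390 to 1776, 1461 to 1626), 1805 to 2270 for TCP (1074 to 1256, 724 to 1014), 3294 to 4667 against ATRA (1824 to 2429, 1397 to 2238), 2183 to 3411 against TCP (1146 to 1734, 1028 to 1677) and 456 to 1342 for the interaction (259 to 704, 186 to 638). Treated against baseline had 0 to 1 genes (0 higher, 0 to 1 lower) and AML against MDS 0 to 6 (0 to 1 higher, 0 to 5 lower).

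Values that changed sign had not passed the threshold in the fit as planned. In treated against baseline, ITGAM was at -0.49 by limma-voom with the patient as block, -0.23 with no disease covariate, -0.24 in AML alone and -0.030 in libraries with 1000000 counts. Leaving out 1 library at a time, it ranged from -0.69 to 0.48, with -0.14 without 1 baseline MDS, -0.67 without 1 treated MDS and -0.69 without 1 treated AML library. RARA was at 0.12 by limma-voom with the block and ranged from -0.95 to 0.37 (without 1 baseline MDS library), and RXRA was at 0.029 in libraries with 1000000 counts. In AML against MDS, the ranges were -4.46 to 1.10 for MT-ND4L, -3.28 to 0.26 for MT-ND2, -0.22 to 8.55 for RARA and -0.63 to 7.85 for RXRA, reversed without 1 MDS library, and -6.70 to 1.47 for CRHBP and -6.77 to 5.30 for IL1RL1, reversed without the other.

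For TCP in SKNO-1, CYP26A1 ranged from -3.09 (without TCP replicate 1) to 3.24, with -0.77 without control replicate 1. KDM1A in SKNO-1 ranged from -0.031 to 0.0076 for ATRA (highest without ATRA replicate 1), from -0.089 to 0.0025 against ATRA (highest without ATRA+TCP replicate 1) and from -0.0034 to 0.087 against TCP (lowest without ATRA+TCP replicate 2). For TCP in U-937, KDM1A ranged from -0.015 to 0.0076 (highest without control replicate 1, and 0.0056 without TCP replicate 1), RARA from -0.18 to 0.087 (highest without control replicate 2) and RXRA from -0.29 to 0.064 (highest without TCP replicate 1, and 0.026 without control replicate 2). GFI1 in the U-937 interaction ranged from -0.11 to 0.053 (highest without control replicate 2).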

Other observations

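The genes and list members in this part were chosen after their values were seen. Several genes that rose or fell with ATRA+TCP in both lines were not described above. CHST15, a sulfotransferase gene, rose by 6.95 ± 0.19 in U-937, the macrophage gene MS4A4A by 6.38 ± 0.12 and the lectin gene SIGLEC11 by 6.67 ± 0.27, and all of them also rose in SKNO-1. PTX3, which encodes a soluble pattern recognition molecule, was at -2.44 ± 0.34 in U-937 and -2.36 ± 0.24 in SKNO-1, the chaperone gene CLU at -2.49 ± 0.12 and -1.82 ± 0.35, and the immediate-early gene EGR1 at -2.5 ± 0.36 and -1.89 ± 0.25. Some genes moved apart: CD52 was at 3.08 ± 0.44 in U-937 and -2.64 ± 0.12 in SKNO-1, the signalling adaptor TYROBP at 2.65 ± 0.11 and -2.04 ± 0.28, RNASE2 at 2.18 ± 0.10 and -3.00 ± 0.13, and the lipase gene MGLL at 2.80 ± 0.10 and -2.22 ± 0.14. The reverse was seen for TSPAN7, at -1.56 ± 0.43 in U-937 and 4.37 ± 0.37 in SKNO-1, and WFDC1, at -2.07 ± 0.16 and 2.5 ± 0.15.

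Lists that did not pass in SKNO-1 with ATRA+TCP still held large changes in single genes. Among mast cell, basophil and eosinophil genes 5 of 13 rose and 4 fell (camera adjusted p = 0.902). In the primary granule list 3 of 11 rose and 6 fell (4 and 7 adjusted over the list alone, median -0.84, adjusted p = 0.0975), with CTSG at -2.91 ± 0.22. Drug targets and partners rose in 7 and fell in 5 of 20 cases (8 and 6 adjusted over the list alone, adjusted p = 0.748), with GFI1B 43.7 times higher (45 counts against 1, counting interval 7.45 to 1763) and KDM1B, the paralogue of KDM1A, at -0.93 ± 0.07, and genes associated with the RUNX1-RUNX1T1 fusion rose in 5 and fell in 1 of 10 (5 and 2 adjusted over the list alone, adjusted p = 0.0670), with UBASH3B at 1.65 ± 0.06. CDK inhibition and p53 genes rose in 7 and fell in 5 of 16 (adjusted p = 0.790), with CDKN1A at -1.60 ± 0.22, and in U-937 the value of CDKN1A was 3.08 ± 0.16. MYC was at -0.20 ± 0.06 in SKNO-1 (adjusted p = 0.0108), and its list did not pass (2 higher and 3 lower of 22, or 2 and 2 adjusted over the list alone, adjusted p = 0.0913).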
